A study of Mus musculus with 6 samples.

How the data were processed

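Expression was measured with single-colour microarrays on total RNA from 6 mouse samples, 3 of undifferentiated embryonic stem (ES) cells and 3 of Pax7-GFP cells sorted after 3 weeks of myogenic differentiation. Per the labels' protocols, biotin-labelled cRNA was prepared with a double amplification, and GFP-positive cells were purified by flow cytometry with gates set on undifferentiated cultures of each reporter line. Per the submitters' processing notes, signals were made with RMA (robust multi-array average, which corrects background, normalizes between arrays and summarises the probes of a probe set) in R 2.12.1. The deposited values are these RMA signals on the log2 scale, 1 value per probe set and array. The probe set definition and the RMA options are not given in the sources used here. No genome build is named either, so no coordinates are given. The table held 41345 rows with values from 2.73 to 13.7. Array medians lay between 5.61 and 5.69, so the arrays were used on the deposited scale. RMA compresses the folds of genes near background, and a double amplification can favour the 3' ends of transcripts, so the folds below are those of the log2 signals and not of molecule numbers. No detection calls accompany the values, so a gene near the array median cannot be called absent.

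Groups and replicate numbers were taken from the sample titles, which call the replicates biological. How the cultures were kept apart is not stated, so the p-values measure the spread between these samples. Probe sets were named through GEO's platform annotation of 2022, which listed 25335 of the rows. Of these, 23521 carried 1 gene symbol and 1814 carried several. The other 16010 rows were unnamed here and include any control probe sets, which their identifiers do not mark. Gene identifiers of 23328 single-symbol rows were found in the reference gene table (GRCm38.p6), and 0 symbols changed. A gene was represented by the single-symbol probe set with the highest mean over all 6 arrays. This gave 22180 genes, 1082 of which had several probe sets. No dim gene was left out.

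Pax7-GFP cells were compared with ES cells with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Fold changes are Pax7-GFP minus ES, with the moderated standard error (SE). Group levels are mean ± SD of the log2 signal over 3 arrays. The precision of every value is limited by the number of arrays. The gene lists (21 lists, 407 of 431 genes measured) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 21 lists, with an estimated correlation and with fry as alternatives. The lists cover pluripotency, myogenic factors, satellite cell genes, sarcomere, fusion and excitation, cell cycle and its inhibitors, somitic mesoderm, the Notch pathway, Hox genes, imprinted genes, markers of other cell types (neural, neural crest, fibroblast, endothelial, haematopoietic, cardiac and smooth muscle, endoderm, epithelial), immediate early genes and housekeeping genes. Dlk1, Cdkn1c, Chrna1 and Musk each stood in more than 1 list.

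The gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except those alternatives said to be added later. The rule took 9 anchors, the 5 largest rises and the 5 largest falls with non-overlapping groups, and from each list the 2 called members with the largest change plus the largest called change in the other direction, 62 genes in all. Any other gene named was chosen after its values were seen, and the text says so. The gene fit was tested on simulated data with the ES means and the within-group spreads of the 22180 genes, each gene drawn independently. It called 96 of 100 genes changed by 1.5 on the log2 scale, 100 of 100 changed by 3, and 1 of 21980 unchanged genes. Both simulated groups shared 1 pooled SD per gene, whereas the real median SD was 0.084 in ES and 0.14 in Pax7-GFP arrays. Far fewer genes were changed than the 9126 past the adjusted p threshold in the data. The shares called therefore need not hold for the data. On simulated lists of 20 genes, camera called the 1 list shifted by 1 and 0 of 20 unshifted lists. Because the simulated genes were uncorrelated, this does not check the list p-values for genes that vary together. Alternatives changed the scaling, a signal floor, a filter on dim genes, the probe set rule, the unit tested, the fold threshold, the variance prior, array weights, a replicate block, and the arrays included. An alternative planned for probe sets with suffixes that mark cross-hybridisation was not run, because the identifiers carry none. Background correction could not be varied without scanner files, which were not used here. A list of 27 trophoblast genes was written after values had been seen. Neighbouring genes were taken from the gene order of GRCm38.p6.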

Results

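Gene expression was profiled in undifferentiated mouse ES cells, which are pluripotent, and in Pax7-GFP cells, which were sorted by a green fluorescent reporter of Pax7 after 3 weeks of differentiation toward skeletal muscle. Pax7 is a transcription factor of muscle progenitors and satellite cells. Each group comprised 3 samples, hybridised to 1 array each. The comparison asks how the sorted cells differ from undifferentiated cells. Array medians ranged from 5.61 to 5.69 on the log2 scale, and no pair of arrays was identical. Across 22180 genes, arrays correlated with one another at r = 0.997 within the ES group and at 0.987 to 0.993 within the Pax7-GFP group, against 0.895 to 0.905 between groups. Genes are not independent replicates, so these correlations describe the arrays only. The first principal component carried 91.2% of the variance and separated the groups. The median gene had an SD of 0.084 among ES arrays and 0.14 among Pax7-GFP arrays.

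The sorted cells carried high signals of the muscle determination genes and low signals of most pluripotency genes. Pax7 itself, measured by probe set 17431910, rose from 5.70 ± 0.073 (SD, n = 3) in ES cells to 10.90 ± 0.25 (SD, n = 3) in Pax7-GFP cells, a log2 fold change of 5.20 (SE 0.13) or 36.8-fold (limma, adjusted p = 3.93e-08). The sort on a Pax7 reporter selects for this rise, so it checks the sort and is no separate finding. Nanog, a core pluripotency factor measured by probe set 17462694, went from 12.02 ± 0.072 to 5.13 ± 0.15 (SD, n = 3 each), a log2 fold change of -6.89 (SE 0.10, limma, adjusted p = 1.00e-08). In all, 3212 of the 22180 genes were called at an adjusted p under 0.05 and at least a 2-fold difference, 1627 higher and 1585 lower in Pax7-GFP cells. A gene past the p threshold alone, with a smaller difference, was not called. At least 4-fold differences were found for 537 higher and 473 lower genes. The groups did not overlap in 3211 of the called genes. The call itself selects for this arrangement, so the count is no separate support. The median log2 fold change over all genes was 0.024. Without a minimum fold 9126 genes passed, and a limma test against a 2-fold difference called 1713.

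**Figure D1:**
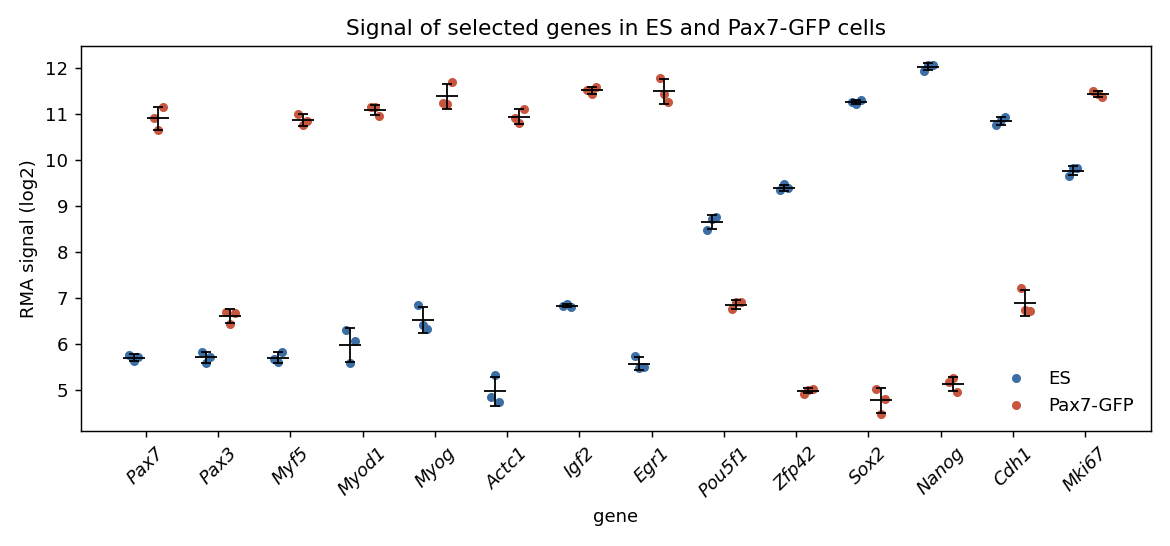
RMA signal (log2) of 14 genes in each of the 3 ES arrays (blue) and 3 Pax7-GFP arrays (red), with the mean and SD in black. The means of Pax7, Myf5, Myod1 and Myog lie between 10.86 and 11.37 in Pax7-GFP cells and at or below 6.53 in ES cells, while Nanog and Sox2 show the opposite arrangement.

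The 5 largest rises were those of Car3, Capn6, Islr, Actc1 and Egr1. Car3, a carbonic anhydrase abundant in slow muscle and fat, rose by 6.66 (SE 0.18) on the log2 scale, from 5.35 ± 0.40 to 12.01 ± 0.12 (SD, n = 3 each). With the mean of its probe sets Car3 stood at 5.55, below the other 4 rises. Capn6, a calpain family member, rose by 6.56 (SE 0.14), and Islr, a secreted leucine-rich repeat protein, by 6.27 (SE 0.13). Actc1, the cardiac actin that embryonic skeletal muscle also uses, rose by 5.97 (SE 0.16). The 5 largest falls were those of Zfp981, Gm21082, Tdgf1, Fbxo15 and Zfp640, with log2 fold changes of -7.96, -7.15, -7.13, -7.12 and -7.03. Zfp981, Gm21082 and Zfp640 may have close copies elsewhere, so their probe sets are uncertain to single copies. With a signal floor Zfp640 stood at -6.43, behind Nanog at -6.89, so its place among the 5 rests on values near background. These 10 genes had limma adjusted p-values between 5.12e-09 and 6.22e-08.

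Pluripotency genes fell as a group. Of 28 measured members, 26 were lower, 0 were higher and 2 were not called (0 past the p threshold alone), and the median log2 fold change was -3.88 (camera, adjusted p = 5.48e-22, and adjusted p = 0.0389 with an estimated correlation). The largest falls were those of Tdgf1, a Nodal co-receptor, and Fbxo15, a target of Oct4. Sox2 fell by 6.48 (SE 0.13) to 4.77 ± 0.27 and Zfp42, also known as Rex1, fell by 4.41 (SE 0.081) to 4.99 ± 0.060 (SD, n = 3 each, limma adjusted p = 1.87e-08 and 1.68e-08). Pou5f1, which encodes Oct4, fell by 1.79 (SE 0.10), from 8.64 ± 0.15 to 6.86 ± 0.087 (SD, n = 3 each, limma adjusted p = 3.20e-06). The 2 members not called, named after their values were seen, were Tbx3 and Dppa5a. Tbx3 stayed high, at 10.32 in ES and 10.15 in Pax7-GFP cells, and Dppa5a was low in both, at 5.48 and 5.30. The count adjusted over the list alone was 26.

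Transcription factors of the skeletal muscle lineage rose. Of 22 measured members, 14 were higher, 1 was lower and 7 were not called (3 past the p threshold alone), with a median log2 fold change of 1.90 (camera, adjusted p = 1.82e-09, and adjusted p = 0.0472 with an estimated correlation). Pax7, the gene of the sorting reporter, is among the 14. Eya4, a transcriptional co-activator, rose by 5.25 (SE 0.14). The determination factors Myf5 and Myod1 rose by 5.16 (SE 0.10) and 5.09 (SE 0.17), and Myog, which drives terminal differentiation, rose by 4.85 (SE 0.17) to 11.37 ± 0.27 (SD, n = 3). The adjusted p-values of these 4 genes lay between 1.87e-08 and 2.43e-07 (limma). Pax3, the paralog of Pax7, had a log2 fold change of 0.89 (SE 0.11, limma adjusted p = 0.000210), below the 2-fold minimum. Tead4 was the lower member, at -1.17 (SE 0.18, limma adjusted p = 0.000920). It stood at -0.94 without Pax7-GFP replicate 2, below the 2-fold minimum, so that 0 members were lower. Adjusted over the list alone, 15 members passed.

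Surface and signalling genes of satellite cells and myoblasts had the highest median of the 21 lists, 3.11 on the log2 scale. Of 24 measured members, 19 rose, 0 fell and 5 were not called (4 past the p threshold alone). The list passed camera at adjusted p = 1.92e-14, and at adjusted p = 0.0389 with an estimated correlation. Fgfr4, a fibroblast growth factor receptor of muscle progenitors, rose by 5.08 (SE 0.16), and Met, the receptor of hepatocyte growth factor, rose by 5.07 (SE 0.17). Adjusted over the list alone, 19 members passed. The Notch pathway list had 8 of 17 members higher, 0 lower and 9 not called (5 past the p threshold alone), with a median of 0.58 (camera, adjusted p = 0.000301, and adjusted p = 0.157 with an estimated correlation). Its largest rises were those of the Notch target genes Hey1, by 4.64 (SE 0.12), and Heyl, by 4.03 (SE 0.18). The count adjusted over the list alone was 8.

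Many genes of differentiated muscle, though not all, were higher in Pax7-GFP cells. Each array measured many sorted cells together, so whether these genes and Pax7 were high in the same cells is not known. In the sarcomere list, 22 of 32 measured members were higher, 1 was lower and 9 were not called (5 past the p threshold alone), with a median of 1.69 (camera, adjusted p = 1.64e-12, and adjusted p = 0.101 with an estimated correlation). Mybpc1, a slow-type myosin binding protein, rose by 4.76 (SE 0.098). Mylpf, a fast myosin light chain, fell by 1.83 (SE 0.16), from 8.63 ± 0.13 to 6.80 ± 0.33 (SD, n = 3 each, limma adjusted p = 3.85e-05). In the list for fusion, excitation and the neuromuscular junction, 14 of 26 rose, 0 fell and 12 were not called (8 past the p threshold alone), with a median of 1.15 (camera, adjusted p = 1.82e-09, and adjusted p = 0.132 with an estimated correlation). Without Pax7-GFP replicate 3, 1 member of this list fell. Atp2a1, the fast muscle calcium pump, rose by 4.70 (SE 0.22). Mymk, the fusion protein myomaker, rose by 4.34 (SE 0.32), with an SD of 0.76 among Pax7-GFP arrays. Mymx, another fusion gene, named after its values were seen, went the other way. It stood at -0.94 (limma adjusted p = 0.000605), short of the 2-fold minimum. The counts were 23 and 14 when each was adjusted over the list alone. The members past neither threshold, named after their values were seen, were Myh4 at 0.20, Tcap at 0.18, Myh2 at 0.13 and Mybpc2 at -0.085 in the sarcomere list, and Jam3 at 0.39, Srl at 0.27, Casq2 at 0.15 and Ckm, the muscle creatine kinase, at 0.084 in the other. Myosin heavy chains share sequence, so probe sets of this family may not separate them.

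Most cell cycle genes differed by less than 2-fold, while most inhibitors of the cycle rose. Of 25 measured cell cycle genes 2 were higher, 3 were lower and 20 were not called (14 past the p threshold alone), and the median was -0.36 (camera, adjusted p = 0.00251 toward lower values, and adjusted p = 0.305 with an estimated correlation). Mki67, which encodes the proliferation antigen Ki-67, rose by 1.66 (SE 0.088) to 11.42 ± 0.067, whereas Mybl2, a transcription factor of the cycle, fell by 2.95 (SE 0.11) to 8.41 ± 0.15 (SD, n = 3 each). With the mean of its probe sets Mybl2 stood at -2.25. The 6 Mcm genes of the replication helicase, named after their values were seen, stood between -1.34 and -0.82, with Mcm2 and Mcm5 called. The list's counts rest partly on single arrays, with 1 higher member without ES replicate 1, and 1 higher and 5 lower members without Pax7-GFP replicate 3. Of 13 measured inhibitors 8 rose, 0 fell and 5 were not called (5 past the p threshold alone), with a median of 2.10 (camera, adjusted p = 1.76e-05, and adjusted p = 0.0905 with an estimated correlation). Ccng2, an atypical cyclin, rose by 3.17 (SE 0.12), and Cdkn2c, the p18 kinase inhibitor, by 3.02 (SE 0.16). The counts were 5 and 8 when each was adjusted over the list alone.

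Imprinted genes were mostly higher. Of 21 measured members 13 rose, 1 fell and 7 were not called (4 past the p threshold alone), with a median of 1.72 (camera, adjusted p = 6.97e-07, and adjusted p = 0.132 with an estimated correlation). Igf2, a fetal growth factor, rose by 4.67 (SE 0.079), from 6.83 ± 0.025 to 11.50 ± 0.075 (SD, n = 3 each, limma adjusted p = 1.33e-08). Dlk1, an inhibitor of adipogenesis, rose by 3.73 (SE 0.12). Phlda2, a placental growth restrictor, fell by 1.15 (SE 0.099), and without Pax7-GFP replicate 1 a total of 2 members fell. Hox genes, which mark position along the body axis, had 10 of 36 measured members higher, 0 lower and 26 not called (11 past the p threshold alone), with a median of 0.22 (camera, adjusted p = 0.0192, and adjusted p = 0.157 with an estimated correlation). Hoxa5 rose by 3.26 (SE 0.24) and Hoxa4 by 2.53 (SE 0.19). The counts were 14 and 10 when each was adjusted over the list alone.

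**Figure D2:**
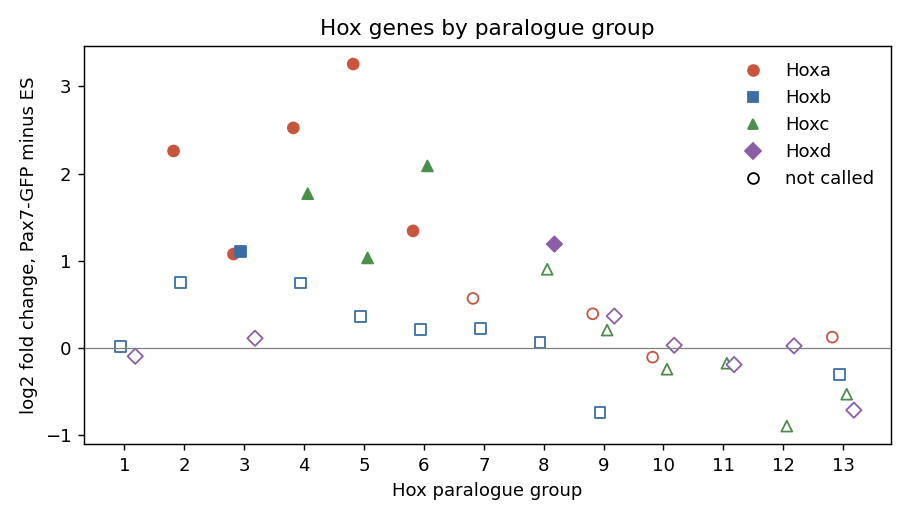
Log2 fold change (Pax7-GFP minus ES) of each of the 36 measured Hox genes against its paralogue group, with called rises filled and other genes open. The 10 called genes lie in groups 2 to 8.

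**Figure D3:**
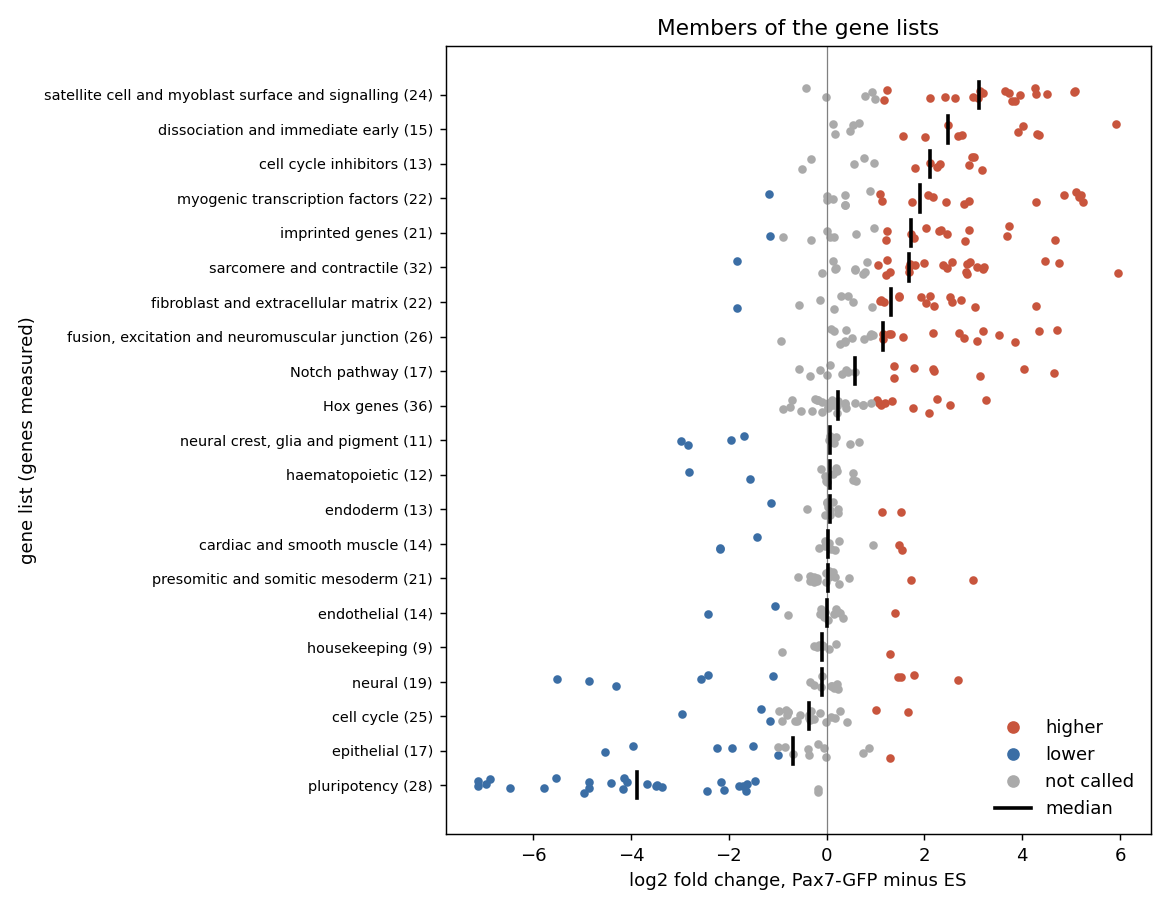
Log2 fold change (Pax7-GFP minus ES) of each measured member of the 21 gene lists, ordered by the list median (black bar), with called rises, called falls and other members in different colours. The satellite cell list has the highest median, 3.11, and the pluripotency list the lowest, -3.88.

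Markers of other cell types that the culture or gate could hold moved apart. The only reference was ES cells, so a rise or fall cannot show which cells the gate held. The fibroblast and extracellular matrix list had 14 of 22 members higher, 1 lower and 7 not called (4 past the p threshold alone), with a median of 1.32 (camera, adjusted p = 1.45e-06, and adjusted p = 0.157 with an estimated correlation). Fap, a fibroblast surface protease, rose by 4.29 (SE 0.20), and Dcn, the matrix proteoglycan decorin, by 3.03 (SE 0.21), while Mfap5 fell by 1.82 (SE 0.13). Epithelial genes were lower in 6 of 17, higher in 1 and not called in 10 (7 past the p threshold alone), with a median of -0.68 (camera, adjusted p = 0.00114, and adjusted p = 0.193 with an estimated correlation). Epcam, an epithelial adhesion molecule, fell by 4.53 (SE 0.12) and Cdh1, which encodes E-cadherin, fell by 3.96 (SE 0.14), or stood at -3.01 with the mean of its probe sets. Both started from high ES levels, at 9.91 and 10.85. The keratin Krt8 rose by 1.29 (SE 0.12). Adjusted over the list alone, the counts were 15 and 7.

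The remaining cell type lists did not pass camera as groups. Among neural genes 4 of 19 were higher and 6 lower (camera, adjusted p = 0.307). The largest falls started from high ES levels, as for Stmn2, a microtubule regulator, at 10.95 ± 0.027 and Nefl, a neurofilament, at 9.31 ± 0.082 (SD, n = 3 each), with log2 fold changes of -5.51 and -4.85. Zic1, a dorsal neural and somitic factor, rose by 2.68 (SE 0.17). The neural crest, glia and pigment list had 4 of 11 lower and 0 higher (camera, adjusted p = 0.374), led by Tfap2a at -2.97 and Pmel at -2.83. Its median, 0.078, differs in sign from its mean, -0.70, and the test ran toward lower values. Endothelial genes were higher in 1 and lower in 2 of 14 (camera, adjusted p = 0.872), with a median of 0.0020, a mean of -0.14 and a test toward lower values. Cdh5, an endothelial cadherin, rose by 1.41 (SE 0.26), and Pecam1 fell by 2.43 (SE 0.12). Without Pax7-GFP replicate 1 there was 1 lower endothelial gene.

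Haematopoietic genes had 2 of 12 lower, Laptm5 at -2.81 and Cd68 at -1.56, and 0 higher (camera, adjusted p = 0.919). Cardiac and smooth muscle genes had 2 of 14 higher, Acta2 among them at 1.53, and 3 lower, among them Cnn1 at -2.18 and Tbx20 at -2.17 (camera, adjusted p = 0.930). In both lists the median was above 0, at 0.065 and 0.038, and the mean below it, at -0.19 and -0.10, with camera toward higher and fry toward lower values. Endoderm genes had 2 of 13 higher, among them Dab2 at 1.52, and 1 lower, Apoa2 at -1.13 (camera, adjusted p = 0.726). Presomitic and somitic mesoderm genes were higher in 2 of 21, Lfng at 3.00 (SE 0.21) and Foxc1 at 1.72 (SE 0.16), and lower in 0 (camera, adjusted p = 0.919). Adjusted over the list alone, called members numbered 10 neural, 4 neural crest, 3 endothelial, 2 haematopoietic, 5 cardiac and smooth muscle, 3 endoderm and 2 somitic.

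Immediate early genes, which respond within minutes to growth factors and to tissue dissociation, were higher in Pax7-GFP cells. Of 15 measured members 10 rose, 0 fell and 5 were not called (1 past the p threshold alone), with a median of 2.49 (camera, adjusted p = 1.17e-07, and adjusted p = 0.157 with an estimated correlation). Egr1 rose by 5.91 (SE 0.14), from 5.58 ± 0.14 to 11.48 ± 0.26 (SD, n = 3 each), and Fos by 4.34 (SE 0.18), both transcription factors of this class. The 5 members not called, named after their values were seen, were Hspa1b at 0.65, Ier3 at 0.53, Hspa1a at 0.47, Dusp1 at 0.17 and Socs3 at 0.14. Whether the ES cells were sorted in the same way is not stated. Housekeeping genes had 1 of 9 measured members higher, B2m, the light chain of major histocompatibility class I, by 1.30 (SE 0.10), and 0 lower (camera, adjusted p = 0.663). Adjusted over the list alone, the counts were 10 and 1. Of the 21 lists, 13 passed camera at the preset correlation and 3 with an estimated one.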

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

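The test of single-symbol probe sets and the counts of list members without single arrays were added after seeing the data. Changing the scaling, signal floor, dim-gene filter, mean of probe sets, variance prior, array weights or replicate block left between 2734 and 3223 genes called, of which 49.0% to 52.0% were higher. Without single arrays 3169 to 3309 genes were called, and 2992 to 3146 of the 3212 calls were kept in the same direction. Thresholds and the unit tested moved the counts by construction. Without a minimum fold 9126 genes passed (4378 higher, 4748 lower), at a 4-fold minimum 1010 (537 and 473), and in a limma test against 2-fold 1713 (879 and 834). Testing all 41345 rows called 4951 (2583 lower), and single-symbol probe sets 3363.

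With an estimated correlation 10 lists no longer passed camera, at adjusted p = 0.101 for sarcomere, 0.132 for fusion and excitation, 0.305 for cell cycle, 0.0905 for inhibitors, 0.157 for Notch, 0.157 for Hox, 0.132 for imprinted, 0.157 for fibroblast, 0.193 for epithelial and 0.157 for immediate early genes. Under their other alternatives the adjusted p of these lists reached at most 0.0451, for Hox genes. Under fry, which does not compare a list with other genes, 3 more lists passed, neural at 6.13e-05, neural crest at 0.000120 and endothelial at 0.0208, against 0.0598 or more under their other alternatives. The cause was not tested. No called list or named gene changed direction under the alternatives run for it. Named genes were followed under the scalings, the floor, the mean of probe sets, the replicate block and the left-out arrays. Among these settings Tead4 alone lost its call, at -0.94 without Pax7-GFP replicate 2. A 4-fold minimum ends the calls of smaller changes by construction, such as Pou5f1 at -1.79. By over 1.5 times in fold, the mean of probe sets moved Car3 to 5.55, Cdh1 to -3.01 and Mybl2 to -2.25, and the floor moved Zfp640 to -6.43. Leaving out suffixed probe sets was not run, since identifiers carry no suffix.

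Whether same-numbered samples were prepared together is not stated. Their deviations from the group means correlated at -0.108, -0.22 and 0.00695, so no pairing by number was seen, though so few arrays cannot exclude it. No sample correlated best with its own number. The replicate block called 3213 genes (1628 higher, 1585 lower). No detection calls accompany the values, so signal over background was not judged per gene.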

Other observations

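The tests in this part were chosen, or had their criteria written, after the results were seen, while the Hox, immediate early and epithelial lists they draw on were fixed earlier. Several groups of neighbouring genes moved together. In 1 zinc finger cluster, from Smarca5-ps to Zfp984 in the gene order of GRCm38.p6, 16 of 18 measured genes were lower in Pax7-GFP cells, with a median log2 fold change of -4.44. They include Zfp980 at -6.11, Rex2 at -6.65 and Zfp534 at -5.92. Genes named Zfp followed by a number were lower in 14.9% of 370, against 7.02% of other genes. Outside the cluster the share was 12.7% of 361. These genes were noticed for their falls, so the shares are descriptive. Of 22 measured protocadherin beta genes, which encode adhesion molecules, 12 rose and 0 fell. These were Pcdhb11 to Pcdhb22 without a gap, from 1.12 to 2.86 on the log2 scale, and their probe sets are uncertain between copies. Pcdhb12 and Pcdhb21, at 4.31 and 3.47 in ES cells, lay under the signal floor of 4.45 there. In Pax7-GFP cells they reached 5.43 and 4.70. Raised to the floor, both would miss the 2-fold minimum, so the unbroken run rests on dim values. Between Dlk1 and Dio3, an imprinted domain rich in small RNAs, 37 of 55 placed genes rose and 0 fell, with a median of 1.23. Most of these are small RNAs, which are not independent genes if they share transcripts. Some called ones were dim in both groups, such as Mir376a at 3.23 in ES and 4.23 in Pax7-GFP cells. Meg3 stood at 0.98 and was not called, and Dio3 stood at -0.0065.

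The 10 Hox genes that rose lay in paralogue groups 2 to 8, and 0 of 15 measured genes of groups 9 to 13 rose, a boundary placed after the calls were seen. Among the 10, Hoxc5, named after its values were seen, went from 4.14 in ES to 5.17 in Pax7-GFP cells. Its ES level lay under the signal floor of 4.45, so its call rests on dim values. Without single arrays 9 to 11 Hox genes rose. Within groups 1 to 8 the counts differed between clusters, with 5 of 6 genes higher in HoxA, 1 of 8 in HoxB, 3 of 4 in HoxC and 1 of 3 in HoxD, a difference that was not tested. Among the 16010 unnamed rows, 615 were higher and 726 were lower.

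The neighbour pattern extends beyond these clusters. With 22126 genes placed, 517 neighbouring pairs were called the same way, against a mean of 232.3 and a highest value of 283 in 10000 shuffles of the calls, so 0 shuffles reached it and chance order is argued against. Signal shared between similarly named neighbours may not be the whole cause, since 327 such pairs were counted among differently named neighbours, against at most 215 in shuffles. The shuffles also placed calls within families of similarly named genes, which can lower their counts. Names were compared as text only, so neighbours that may share signal, such as Hoxaas3 and Hoxa5, counted as differently named. The comparison is therefore not decisive. For the 16 falling genes of the zinc finger cluster, signal shared between near-identical copies cannot be told apart from separate falls, because probe sequences were not used here. A candidate explanation is regulation of whole chromosomal domains that differs between the groups, which was not tested.

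Some placental genes were among the larger rises, Tpbpa from 4.81 ± 0.30 to 10.13 ± 0.77 (SD, n = 3 each, limma adjusted p = 6.44e-06) and Prl7b1, Prl2a1 and Tpbpb by 4.63, 3.19 and 2.09. All 4 were highest in Pax7-GFP replicate 1, the array with the lowest weight, 0.376, with Tpbpa at 10.87 against 10.18 and 9.33 and Tpbpb at 7.07 against 5.41 and 5.30. Trophoblast cells that passed the GFP gate stay open, since 24 other measured trophoblast genes, 2 of them also in other lists, had a median log2 fold change of 0.040 (0 higher, 3 lower) at a median level of 4.74 in Pax7-GFP cells, below the array medians. Of the brighter members Krt7, Synb, Pcdh12 and Ascl2 stood at 0.24, 0.25, 0.052 and -0.57. In the epithelial list Krt8 rose by 1.29. Krt18 at 0.88 and Krt19 at 0.73, named after their values were seen, were not called. Epcam and Cdh1 fell by 4.53 and 3.96 from high ES levels of 9.91 and 10.85. Such falls could occur with or without trophoblast cells in the gate, so they do not decide the question. Signal shared between prolactin paralogs stays open at such low levels, with a highest log2 fold change of 1.44 among the other 20 rows of the family at a median level of 4.03, and so does expression by the sorted cells, which was not tested.

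The rise of immediate early genes may come from handling. Over the 15 genes the mean level was 7.19 ± 0.065 in ES and 9.59 ± 0.25 in Pax7-GFP cells (SD, n = 3 each), with Pax7-GFP replicate 1 highest at 9.87 against 9.49 and 9.41. A single badly handled array is argued against, as the lowest Pax7-GFP array lay 2.15 above the highest ES array. Dissociation and sorting of the Pax7-GFP cells alone cannot be told apart from a difference between the cell types for the 10 genes that rose, because no ES sample is known to have been sorted the same way. A biological difference in signalling between the groups is equally untested.

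The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3212 genes and the highest other 0 (limma, with 89 to 559 genes at an unadjusted p under 0.05 in the other splits, against 10431), and 1 split, the real one, reached the real count. For lists passing camera the real split gave 13 and the others 4 to 12, again with 1 split reaching the real count. Every other split set unequal numbers of both groups on each side. It therefore kept part of the group difference and widened the spread within each side. The counts of the other splits are thus no measure of what chance gives, for genes or for lists.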
